A study of Caenorhabditis elegans with 9 samples.

How the data were processed

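RNA was measured in 9 libraries of whole Caenorhabditis elegans hermaphrodites of the wild-type strain N2 at an age of 5 days. The labels place 3 libraries in each of 3 RNA interference (RNAi) groups: L4440, the empty feeding vector that serves as control, B0395.3 and H28O16.1. The last name is the sequence name of atp-1. Replicates were numbered within a group by the order of their records, so a number names a library and pairs nothing. The labels do not say whether the libraries of a group came from separate cultures, so p-values measure the spread between these libraries, which may be technical. The libraries were made with the Illumina TruSeq RNA Library Preparation Kit v2, per the labels' protocols. That kit selects poly(A) RNA and does not mark strand, so reads of a gene and of a partner on the opposite strand could not be told apart.

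The deposited count table holds whole-number counts per gene, with 1 column per library, made by the authors with no normalization. The submitters' processing notes name bcl2fastq 1.8.4, STAR 2.4.1d, featureCounts 1.4.6-p4 and the genome build WBcel235. The roles of these tools, the annotation release and the counting parameters are not given in the sources used here, so it is open how reads shared by near-identical genes were counted. A second deposited table gives RPKM for the same libraries. Its values equal counts divided by gene length and by a library total, but the authors' totals run down the genes in a repeating cycle of 9, so 11.1% of the values were divided by the total of their own library. The total used was between 0.762 and 1.31 times the own total. This was tested on 3629 genes with over 2000 counts in every library: the gene length implied by a value had a median coefficient of variation across libraries of 0.000326% with the cycled totals and of 11.9% with the own totals. The counts were therefore used for every main result. The RPKM table was used as planned for alternatives, and RPKM rebuilt with own totals was added after the data had been seen.

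The table lists 46748 gene identifiers, of which 46449 are in the Ensembl 115 annotation of WBcel235 and 299 are not. The latter held between 0.155% and 0.179% of the counts of a library. Names and coordinates were taken from that annotation. Mitochondrially encoded protein genes without a name there appear under the symbol of the RefSeq gene that they overlap most (ATP6, ND1 and so on). The libraries held between 31236614 and 40990685 counts, and 18727 to 20420 genes had a count. A filter on low counts (filterByExpr, minimum count 10) kept 14622 genes and removed 32126, which held at most 0.0463% of the counts of a library. Log2 CPM (counts scaled to a common library size) correlated across genes with r between 0.994 and 0.997 within groups and between 0.960 and 0.990 between groups. The chi-square per degree of freedom between libraries of a group lay between 2.59 and 16.8, so no pair differed by as little as sampling noise. H28O16.1 replicate 3 lay farthest from its group, at 16.8 and 12.2 to replicates 1 and 2, which stood at 5.51 to each other.

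Genes were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, a quasi-likelihood fit over all 9 libraries and a two-sided F-test for each pair of groups. P-values were adjusted by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 are called changed. Adjusted p-values of genes come from this test unless another tool is named. The biological coefficient of variation was 4.64%. CPM are TMM-scaled and are given as mean ± SD. An exact permutation test of 3 libraries against 3 cannot go below 0.1, so single genes were tested only within this model. On simulated counts with 200 changed genes, the test recovered 67.2%, 80.6% and 97.0% of genes changed 1.5-fold, 2-fold and 4-fold in the H28O16.1 comparison with L4440, with 11 false calls among 14391 unchanged genes. The same simulation of the B0395.3 comparison recovered 70.1%, 88.1% and 93.9%, with 18 false calls among 14392. Far fewer genes changed there than the 8417 and 3976 called in the data, and each gene was drawn independently. The simulation could therefore not show error rates where a large share of genes moves.

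The groups, the comparisons, the tests, 38 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule names both RNAi targets, and the 10 largest rises and 10 largest falls among changed genes with a mean of at least 5 CPM in the libraries compared and no overlap between the groups. From each list it takes up to 4 measured members with the smallest p. Genes outside the rule are said to be chosen after their values were seen. Lists were tested with camera in limma 3.58.1, which asks whether members moved more than other genes, at a preset correlation of 0.01, with adjustment over the 38 lists of a comparison. The test was repeated with a correlation estimated for each list. It was also replaced by fry, which asks whether members move on balance one way and does not compare them with other genes. The RNAi targets were left out of the list tests, and 5 list members found no match in the annotation. On simulated counts all 3 list tests found a list of 30 genes raised 1.3-fold, and none of them called any of 37 unchanged lists. Each gene was drawn independently there, so the simulation could not show how the tests behave on lists whose members vary together. In the data the estimated correlation reached 0.905, for cytosolic ribosomal proteins in H28O16.1 against L4440.

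Alternatives were DESeq2 1.42.0 with its own size factors, RLE factors in edgeR, no filter, a filter at a mean of 50 counts, the 6 libraries compared alone, a test against a fold of 1.5, limma on log2(RPKM + 1) and on log2(RPKM + 0.1), and leaving out each library in turn. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.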

Results

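Polyadenylated RNA was sequenced from whole hermaphrodite worms fed bacteria that carried 1 of 3 RNAi constructs, and expression is given in CPM, counts scaled to a common library size. The control construct was the empty vector L4440. The second construct targeted B0395.3, a gene annotated as a carnitine O-acyltransferase relative. The third targeted H28O16.1, which is atp-1, the alpha subunit of the F1 part of mitochondrial ATP synthase. There were 3 libraries per group, with totals of 37279334 to 40227801 counts in L4440, 34805871 to 40990685 in B0395.3 and 31236614 to 40218034 in H28O16.1. The first principal component of log2 CPM held 71.7% of the variance and separated H28O16.1 from the other groups, and the second held 13.3% and separated L4440 from B0395.3. On the third component, with 3.95% of the variance, H28O16.1 replicate 3 stood at -25.7, apart from replicates 1 (18.5) and 2 (6.63). The test over all groups called 10121 of 14622 genes different among the 3.

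**Figure D1:**
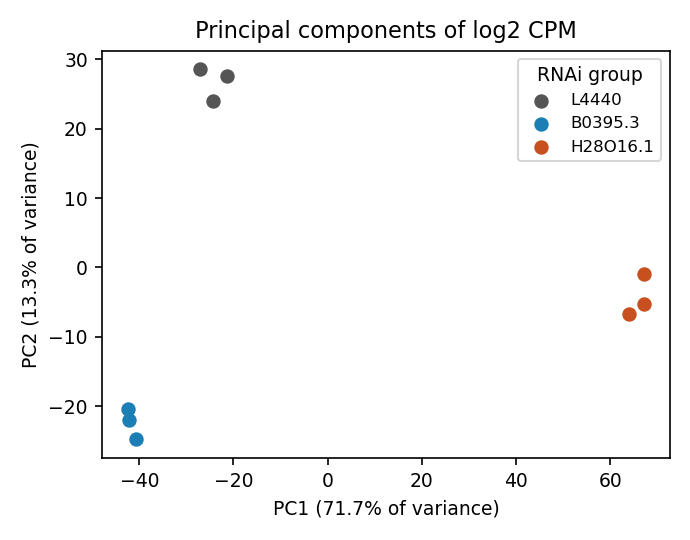
Each point is 1 of the 9 libraries, placed by its first (x axis, 71.7% of variance) and second (y axis, 13.3% of variance) principal component of log2 CPM and coloured by RNAi group. The 3 libraries of each group lie together and apart from the other groups.

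The targeted mRNAs were lower in the libraries labelled with their RNAi. The atp-1 gene (WBGene00010419) lies on chromosome I from 12652277 to 12654655 on the plus strand of WBcel235 and has 1 annotated transcript with 5 exons. Its mRNA stood at 1945 ± 72 CPM (SD, n = 3) in L4440 and at 70.7 ± 4.35 CPM in H28O16.1, or 3.63% of the control. The log2 fold change was -4.78 (SE 0.05, adjusted p = 2.93e-15). In B0395.3 it stood at 1762 ± 50.2 CPM (log2 fold change -0.14, adjusted p = 0.0245), a difference that no longer passed without L4440 replicate 1 (adjusted p = 0.0847), L4440 replicate 2 (0.102), B0395.3 replicate 1 (0.0655) or B0395.3 replicate 3 (0.108). The B0395.3 gene (WBGene00007175) lies on chromosome X from 16035036 to 16040257 on the minus strand and has 3 annotated transcripts with 11 to 12 exons. Its mRNA stood at 33.6 ± 1.77 CPM in L4440 and at 13.9 ± 2.23 CPM in B0395.3, or 41.5% of the control (log2 fold change -1.28, SE 0.10, adjusted p = 7.36e-07). It was also lower in H28O16.1, at 25.6 ± 2.52 CPM (log2 fold change -0.39, adjusted p = 0.00297). Which part of each gene the constructs covered is not given in the sources used here, and reads from a construct would be counted with the gene.

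**Figure D2:**
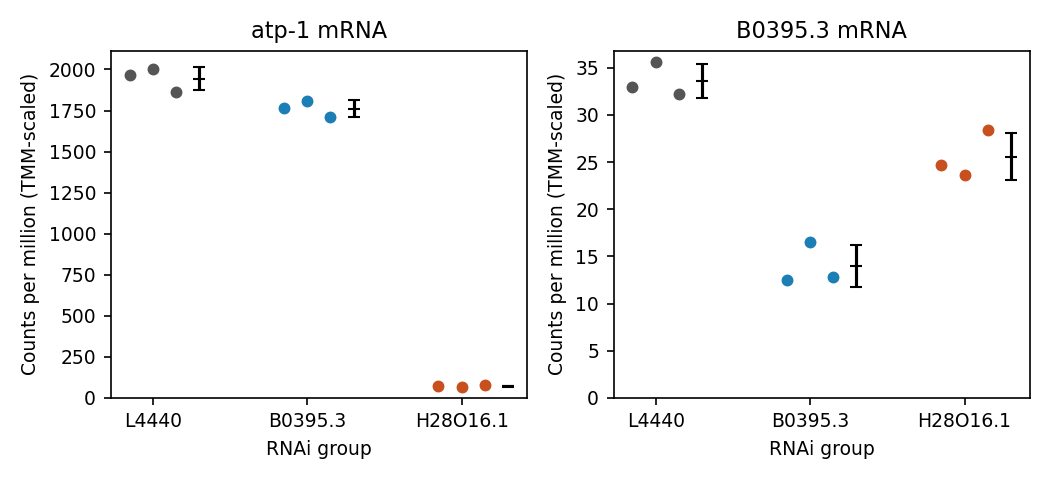
TMM-scaled CPM (y axis) of atp-1 mRNA (left) and B0395.3 mRNA (right) in each library of the 3 RNAi groups (x axis), with points for libraries and the bar beside them for mean ± SD (n = 3). The H28O16.1 libraries average 70.7 CPM of atp-1 against 1945 in L4440, and the B0395.3 libraries average 13.9 CPM of B0395.3 against 33.6 in L4440.

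H28O16.1 RNAi was compared with the empty vector to see which transcripts change in worms treated against atp-1. The largest falls included genes first transcribed in the early embryo. The T-box transcription factor gene tbx-38 fell from 9.99 ± 0.467 CPM (SD, n = 3) to 0.123 ± 0.0968 CPM (log2 fold change -6.37, SE 0.21, adjusted p = 8.17e-11). The early zygotic transcripts sdz-28 and vet-6 fell by 4.44 and 4.43 log2 units. The largest rise was in C07G1.7, from 0.349 ± 0.172 to 19.9 ± 1.18 CPM (log2 fold change 5.84, SE 0.23, adjusted p = 3.27e-10), and the glycolytic aldolase gene aldo-1 rose from 29.5 ± 3.06 to 141 ± 15.1 CPM.

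Besides tbx-38, sdz-28, vet-6 and the target, the 10 largest falls took in fbxb-17, an F-box gene, at -5.04, the Skp1-related ubiquitin ligase genes skr-9, skr-8 and skr-10 at -4.90, -4.47 and -4.46, the cuticle collagen gene col-129 at -4.74 and sepa-1 at -4.40. The product of sepa-1 is an autophagy substrate in embryos. After C07G1.7 and aldo-1 (2.26), the largest rises were the pseudogene M116.2 (2.26), the neuropeptide receptor gene pdfr-1 (2.13), the nuclear hormone receptor gene nhr-6 (2.08), the insulin-like peptide gene ins-7 (1.78), W07E6.5 (1.76), the myo-inositol transporter gene hmit-1.1 (1.75), F57H12.6 (1.65) and the acyltransferase-family gene oac-14 (1.64). All of these passed the test, and none had overlapping groups. Members of the skr, fbxb, tbx and col families can share reads with close copies, so the split between members is uncertain. Antisense genes cover 34.5% of the exon bases of W07E6.5 (nsun-1), 2.8% of those of tbx-38, 2.1% of those of pdfr-1, and 3.1% (C48D5.3) and 2.4% (C48D5.8) of those of nhr-6.

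**Figure D3:**
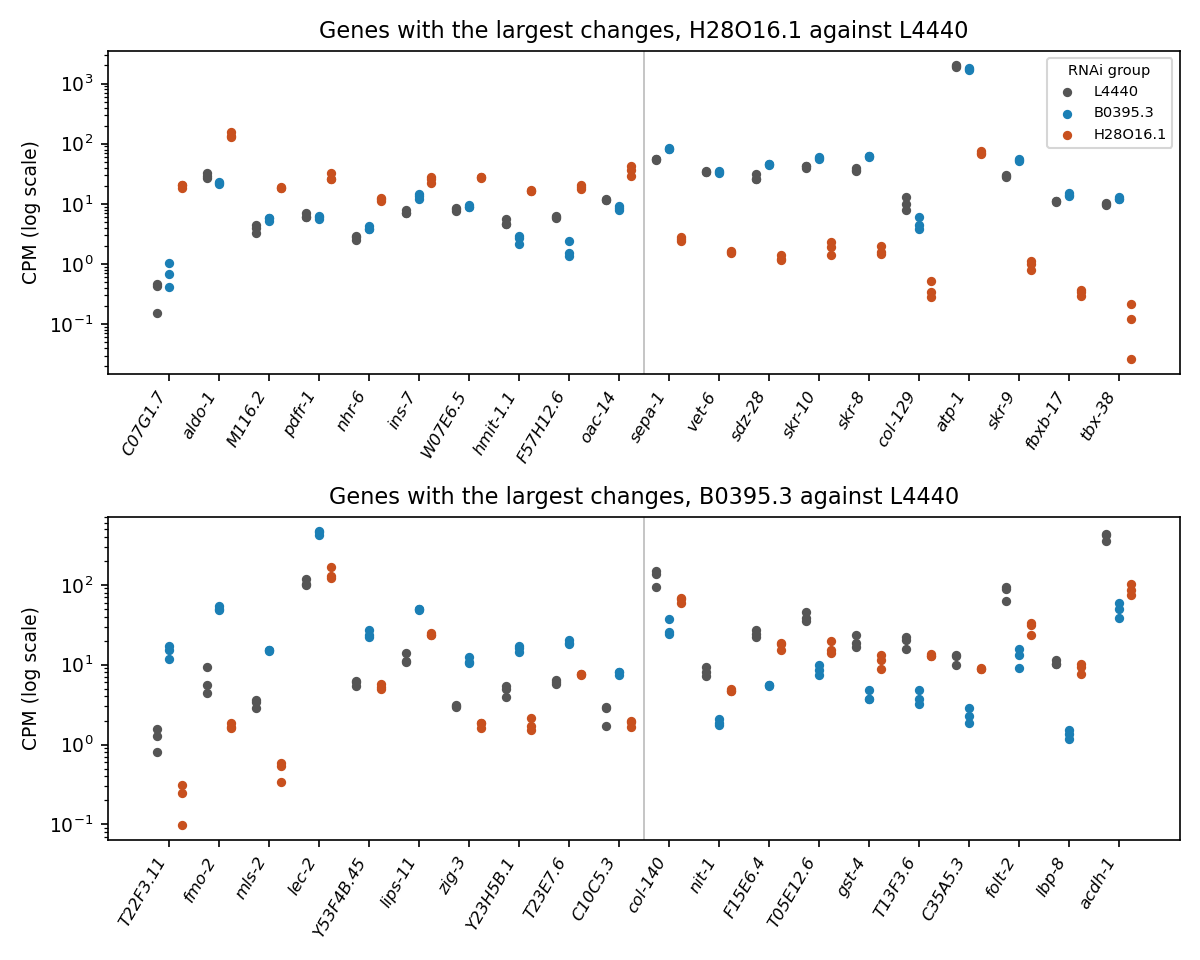
CPM on a log scale (y axis) of the 10 largest rises (left of the line) and 10 largest falls (right of the line) in H28O16.1 against L4440 (top) and in B0395.3 against L4440 (bottom), with each point 1 library coloured by RNAi group. In H28O16.1, tbx-38 averages 0.123 CPM against 9.99 in L4440, and in B0395.3, acdh-1 averages 49.4 CPM against 405.

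Most measured members of the lists of oocyte, sperm and histone genes fell. Of 40 oocyte and early embryo genes, 5 rose, 27 fell and 8 did not pass (5 and 27 adjusted over the list alone), among them the oocyte maturation gene oma-2 (-0.77) and the cyclin B genes cyb-1 (-0.69) and cyb-3 (-0.62). This list was called lower (camera adjusted p = 0.00124, but adjusted p = 0.821 with an estimated correlation). Of 43 measured sperm genes, 3 rose and 27 fell (the same counts adjusted over the list alone), with a median of -1.38. The list was called lower (adjusted p = 0.0318, and adjusted p = 0.783 with an estimated correlation), although the 2 members with the smallest p, spe-41 (1.96) and spe-39 (0.48), rose. The sperm call was lost without H28O16.1 replicate 3 (adjusted p = 0.0774). Of 30 histone genes, 3 rose and 17 fell (3 and 17 adjusted over the list alone), with the linker histone genes hil-3 (-2.88), his-24 (-3.22) and hil-2 (-2.08) and the H3.3 gene his-72 (-0.68) leading. Antisense genes cover 12.9% (M163.16) and 6.0% (M163.19) of the exon bases of his-24. That call (adjusted p = 0.00691) was lost at adjusted p = 0.366 with an estimated correlation, and the rRNA share of the counts was 0.238% ± 0.114 (SD, n = 3) in H28O16.1 against 0.0925% ± 0.00845 in L4440, with replicate 2 of H28O16.1 at 0.107%, close to the highest L4440 library (0.102%). The list of embryonic and larval regulators was not called as a whole (5 rose and 10 fell of 25, also adjusted over the list alone, adjusted p = 0.179), but its 4 members with the smallest p all fell: sdz-28, tbx-38, tbx-37 (-4.92) and sdz-31 (-4.97). Of 35 germ line genes, 10 rose and 15 fell (10 and 15 adjusted over the list alone, adjusted p = 0.536), with ifet-1 at -0.81 and car-1 at -0.78.

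Most mitochondrially encoded mRNAs fell. Of 11 measured, 10 fell (10 adjusted over the list alone) and 1 did not pass, with a median of -0.82, led by ATP6 (-1.81), ND1 (-1.17), ND4 (-0.97) and CYTB (-0.82). The call (adjusted p = 0.000866) was lost at adjusted p = 0.783 with an estimated correlation, and the mitochondrial share of the counts fell from 0.651% ± 0.0136 (SD, n = 3) to 0.378% ± 0.0678. It was lowest in H28O16.1 replicate 3, at 0.301% against 0.427% and 0.407% in replicates 1 and 2. The nuclear genes of oxidative phosphorylation went both ways. Among the 16 ATP synthase subunits other than the target, 3 rose and 8 fell (3 and 8 adjusted over the list alone, adjusted p = 0.127), with asg-2 at -0.58, asb-2 at -0.37 and atp-2, the beta subunit, at -0.24. Of 28 nuclear complex I subunits, 10 rose and 6 fell (10 and 7 adjusted over the list alone, adjusted p = 0.315), and of 24 members of complexes II to IV, 5 rose and 14 fell (5 and 16 adjusted over the list alone, adjusted p = 0.143). Of 69 mitochondrial ribosomal protein genes, 31 rose and 24 fell (32 and 25 adjusted over the list alone, adjusted p = 0.288), with mrps-11 at 0.90. The 20 mitochondrial chaperone, protease and import genes that mark the mitochondrial unfolded protein response were not called (6 rose and 8 fell, the same adjusted over the list alone, adjusted p = 0.918). Among them timm-23 (0.88) and ymel-1 (0.25) rose and hsp-60 (-0.55) and atfs-1 (-0.32) fell. The mitochondrial Hsp70 gene hsp-6, chosen after its values were seen, rose by 0.35 log2 units.

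Genes of central metabolism went both ways within lists. Of 18 glycolysis genes, 13 fell and 3 rose (13 and 3 adjusted over the list alone), and the list was called lower (adjusted p = 0.0126, and adjusted p = 0.783 with an estimated correlation). Its members with the smallest p included aldo-1 (2.26) and the lactate dehydrogenase gene ldh-1 (1.29), which rose, beside aldo-2 (-0.80) and gpd-4 (-0.86), which fell. Of 22 genes of propionate and methionine metabolism, 5 rose and 15 fell (5 and 15 adjusted over the list alone, adjusted p = 0.0213, and adjusted p = 0.783 with an estimated correlation), led by cbs-1 (-1.72), sams-3 (-1.33), hphd-1 (-1.61) and acdh-1 (-2.21). Of 23 genes of the tricarboxylic acid cycle and pyruvate dehydrogenase, 3 rose and 14 fell (3 and 14 adjusted over the list alone), with idhb-1 at -0.59 and mdh-1 at -0.42. This call (adjusted p = 0.0242) had an adjusted p = 0.842 with an estimated correlation. Of 44 genes of carnitine acyl transfer and fatty acid oxidation, 10 rose and 18 fell (10 and 19 adjusted over the list alone, adjusted p = 0.127), with ech-7 at -1.98.

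Most measured proteasome, endoplasmic reticulum chaperone and collagen genes fell. Of 33 proteasome subunits, 1 rose and 26 fell (1 and 27 adjusted over the list alone), with pbs-5 at -0.59 and rpn-10 at -0.41 (adjusted p = 2.83e-06, and adjusted p = 0.783 with an estimated correlation). Of 18 endoplasmic reticulum chaperone genes, 2 rose and 13 fell (2 and 13 adjusted over the list alone), with pdi-6 at -0.73 and hsp-3 at -0.65 against xbp-1 at 0.43 (adjusted p = 0.00691, and adjusted p = 0.783 with an estimated correlation). Of 140 genes in the collagen list, 11 rose and 85 fell (11 and 86 adjusted over the list alone), with a median of -0.76 (adjusted p = 0.000668, and adjusted p = 0.842 with an estimated correlation). The 103 col genes made up 10 of these rises and 58 of these falls. The list also held 37 dpy, rol, bli and sqt genes (1 rose and 27 fell). Not all of these encode collagens, for example dpy-23 (-0.64) and dpy-28 (-0.61) do not. Of 29 genes of small RNA and RNAi pathways, 5 rose and 17 fell (5 and 18 adjusted over the list alone), with the Argonaute genes alg-1 (-1.07) and alg-2 (-0.70) lower and the RNA-dependent polymerase gene ego-1 (0.46) higher (adjusted p = 0.0242, and adjusted p = 0.751 with an estimated correlation). The list of targets of the transcription factor DAF-16 and insulin signalling genes (23 measured) was not called (2 rose and 12 fell, the same adjusted over the list alone, adjusted p = 0.0571), with lea-1 at -1.83. Nor were the 6 vitellogenins (2 rose and 3 fell, the same adjusted over the list alone, adjusted p = 0.448) or the 87 antimicrobial effectors (28 rose and 22 fell, the same adjusted over the list alone, adjusted p = 0.536). For the antimicrobial list and the mitochondrial chaperone list the median and mean were below 0 while the test pointed up.

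In all, 8417 of 14622 genes changed in H28O16.1, 3851 higher and 4566 lower, of which 504 rose and 1226 fell over 2-fold. The 3 libraries of each group did not overlap for 61.4% of genes, against 10% given by chance. Of the changed genes 45.8% were higher, against 33.6% of 3622 genes on the deposited RPKM (1218 higher and 2404 lower) and 32% on log2(RPKM + 0.1) (1199 and 2553). On RPKM with own library totals, an alternative chosen after seeing the data, 53% of 8532 were higher (4560 higher and 3972 lower). Camera called 11 of 38 lists lower and 0 higher, with 0 calls left under an estimated correlation (lowest adjusted p = 0.366) and 27 lists called by fry. Other splits of the same 6 libraries called up to 18 lists by camera, while they called 0 genes. Each of these splits mixed the groups, so it kept part of their difference and counted the rest as spread. Neither count is therefore a rate for unchanged groups.

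**Figure D4:**
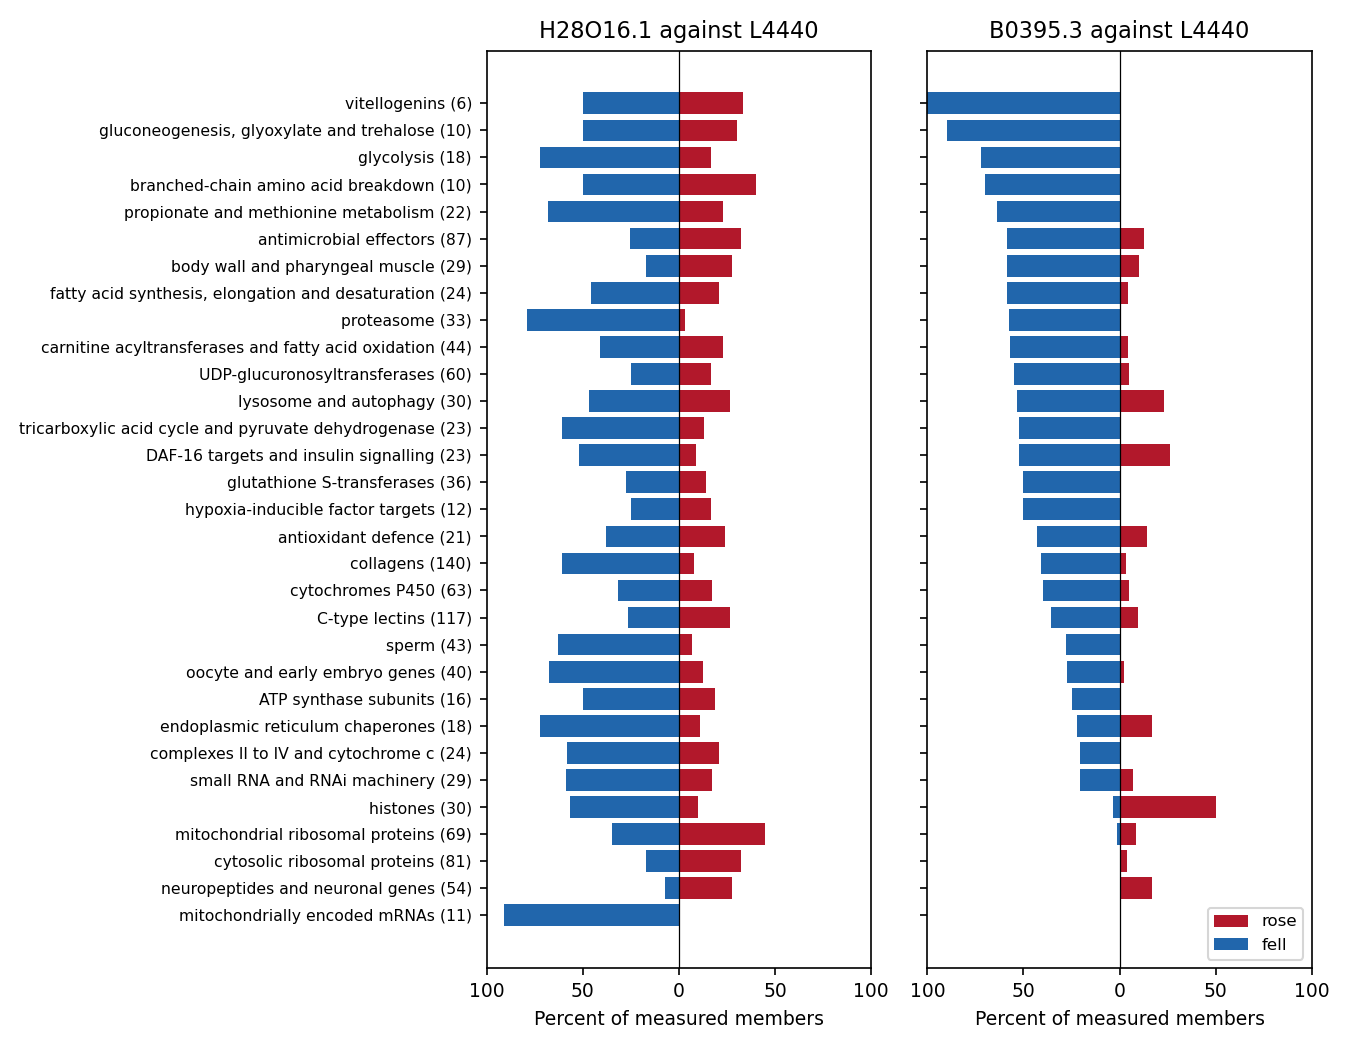
Percent of measured members (x axis) that rose (red, to the right) or fell (blue, to the left) for each gene list that camera called in at least 1 of the comparisons with L4440 (y axis, number of measured members in parentheses), in H28O16.1 (left) and B0395.3 (right). Of 30 histone genes 17 fell in H28O16.1 and 15 rose in B0395.3, and of 11 mitochondrially encoded mRNAs 10 fell in H28O16.1 and 0 passed in B0395.3.

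B0395.3 RNAi was compared with the same controls to see which transcripts change in worms treated against this carnitine acyltransferase relative. The largest fall was in acdh-1, an acyl-CoA dehydrogenase of the propionate shunt, from 405 ± 44.1 CPM (SD, n = 3) to 49.4 ± 10.6 CPM (log2 fold change -3.03, SE 0.14, adjusted p = 8.53e-09). The lysosomal lipid chaperone gene lbp-8 fell from 10.7 ± 0.750 to 1.35 ± 0.171 CPM. The flavin monooxygenase gene fmo-2 rose from 6.42 ± 2.57 to 50.5 ± 3.17 CPM (log2 fold change 2.97, SE 0.17, adjusted p = 5.63e-08), and the galectin gene lec-2 from 107 ± 8.91 to 450 ± 27.7 CPM. In the lists of fat and xenobiotic metabolism, yolk and cuticle genes more members fell than rose, and among histone genes more rose than fell.

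The other large falls were folt-2, of the folate transporter family (-2.66), C35A5.3 (-2.33), T13F3.6 (-2.29), the glutathione S-transferase gene gst-4 (-2.26), T05E12.6 (-2.19), F15E6.4 (-2.15), the nitrilase gene nit-1 (-2.1) and the collagen gene col-140 (-2.09). The largest rise was T22F3.11 (3.59, from 1.21 ± 0.382 to 14.7 ± 2.72 CPM), and after fmo-2 came the homeobox gene mls-2 (2.2), lec-2 (2.08), the non-coding RNA Y53F4B.45 (2.04), the lipase-related gene lips-11 (2.03), the immunoglobulin-domain gene zig-3 (1.90), Y23H5B.1 (1.71), T23E7.6 (1.65) and C10C5.3 (1.65). All passed the test with no overlap between groups. The whole exon sequence of T13F3.6 (100% of its bases) is also covered by T13F3.8 on the opposite strand, so its value is uncertain. Shares covered by other genes were 14.7% for T23E7.6, 8.9% for gst-4, 8.1% for nit-1 and 4.1% for C35A5.3.

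Most genes on the lists of lipid and propionate metabolism fell. Of 44 genes of carnitine acyl transfer and fatty acid oxidation, 2 rose and 25 fell (3 and 31 adjusted over the list alone), with acdh-1, the peroxisomal oxidase genes acox-1.4 (-1.17) and acox-1.5 (-0.91) and ech-6 (-0.65) leading. The list was called lower (adjusted p = 5.28e-08), also with an estimated correlation (adjusted p = 0.0125). Its member acdh-1 is also on the list of propionate and methionine metabolism, so the calls of these lists are not independent. The carnitine palmitoyltransferase gene cpt-4, chosen after its values were seen, rose by 1.62 log2 units. Of 22 genes of propionate and methionine metabolism, 0 rose and 14 fell (1 and 15 adjusted over the list alone), with hphd-1 at -1.95 and hach-1 at -0.71 (adjusted p = 3.50e-07, and adjusted p = 0.114 with an estimated correlation). Of 24 fatty acid synthesis genes, 1 rose and 14 fell (1 and 15 adjusted over the list alone), with the desaturase genes fat-5 (-1.26) and fat-7 (-1.04) lower and fat-3 (0.39) higher (adjusted p = 2.24e-06, and adjusted p = 0.0820 with an estimated correlation). All 6 vitellogenins, which carry lipid into oocytes, fell, also adjusted over the list alone (6), led by vit-3 (-1.51), vit-4 (-1.39) and vit-1 (-1.26). Their share of the counts was 3.00% ± 0.0706 (SD, n = 3) against 4.41% ± 0.0881 in L4440. The vitellogenin call (adjusted p = 2.45e-10) had an adjusted p = 0.0820 with an estimated correlation, and reads of vit-3 and vit-4 can be shared with close copies.

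Most genes on the lists of carbohydrate and amino acid metabolism fell as well. Of 18 glycolysis genes, 13 fell (16 adjusted over the list alone), with gpd-2 at -0.75 (adjusted p = 1.69e-08, and adjusted p = 0.120 with an estimated correlation). Of 10 genes of gluconeogenesis, the glyoxylate cycle and trehalose synthesis, 9 fell (10 adjusted over the list alone), with icl-1 at -1.03 (adjusted p = 1e-08, and adjusted p = 0.114 with an estimated correlation). The tricarboxylic acid cycle list had 12 falls among 23 (13 adjusted over the list alone), with pyc-1 at -0.30 (adjusted p = 5.43e-06, and adjusted p = 0.252 with an estimated correlation). Branched-chain amino acid breakdown had 7 falls among 10 (8 adjusted over the list alone), with bckd-1A at -0.23 (adjusted p = 2.50e-05, and adjusted p = 0.120 with an estimated correlation).

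Detoxification and defence genes formed the next set. Of 36 glutathione S-transferase genes, 18 fell and 0 rose (19 and 0 adjusted over the list alone), with gst-10 at -1.76, and the call (adjusted p = 7.62e-07) held with an estimated correlation (adjusted p = 0.0125). Of 60 UDP-glucuronosyltransferase genes, 3 rose and 33 fell (3 and 35 adjusted over the list alone), with ugt-46 at -1.22 (adjusted p = 9.14e-09, and adjusted p = 0.0820 with an estimated correlation). Of 63 cytochrome P450 genes, 3 rose and 25 fell (3 and 27 adjusted over the list alone), with cyp-35B1 at -1.49 (adjusted p = 2.92e-06, and adjusted p = 0.0820 with an estimated correlation). Of 87 antimicrobial effectors, 11 rose and 51 fell (14 and 52 adjusted over the list alone), with lys-2 at -1.11 and nlp-29 at -1.57 against fmo-2 (adjusted p = 2.65e-10, and adjusted p = 0.114 with an estimated correlation). Of 117 C-type lectins, 11 rose and 42 fell (11 and 43 adjusted over the list alone), with clec-160 at -0.95 (adjusted p = 0.00150, and adjusted p = 0.0820 with an estimated correlation). Lysosome and autophagy genes had 7 rises and 16 falls among 30 (7 and 16 adjusted over the list alone), with the protease gene asp-4 at -0.70 (adjusted p = 0.000624, and adjusted p = 0.162 with an estimated correlation). Antioxidant genes had 3 rises and 9 falls among 21 (3 and 11 adjusted over the list alone), with sod-1 at -0.32 (adjusted p = 0.0135, and adjusted p = 0.349 with an estimated correlation). Hypoxia-inducible factor targets had 6 falls among 12 (6 adjusted over the list alone), with the ferritin gene ftn-1 at -1.83 (adjusted p = 0.00322, and adjusted p = 0.187 with an estimated correlation). The test took no account of whether the factor raises or lowers a target, so this call does not measure its activity.

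Structural genes of cuticle and muscle had more falls than rises. Of 140 genes in the collagen list, 5 rose and 57 fell (8 and 64 adjusted over the list alone), with col-101 at -1.73 and col-95 at -1.4 (adjusted p = 4.82e-08, and adjusted p = 0.349 with an estimated correlation). The 103 col genes held 50 of these falls. Of 29 muscle genes, 3 rose and 17 fell (3 and 20 adjusted over the list alone), with the troponin C gene pat-10 at -0.63 and the troponin T gene tnt-2 at -1.26 (adjusted p = 2.92e-06, and adjusted p = 0.367 with an estimated correlation). Of 33 proteasome subunits, 19 fell (22 adjusted over the list alone), with rpn-1 at -0.19 (adjusted p = 2.25e-07, and adjusted p = 0.349 with an estimated correlation). DAF-16 targets and insulin signalling genes had 6 rises and 12 falls among 23 (7 and 13 adjusted over the list alone), with lea-1 at -0.70 and hsp-12.6 at 1.32 (adjusted p = 0.00986, and adjusted p = 0.349 with an estimated correlation).

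Histones rose more often than they fell: 15 of 30 were higher and 1 lower (20 and 2 adjusted over the list alone), with hil-3 at 1.3, his-24 at 1.12, hil-2 at 0.88 and his-71 at 0.62. The call (adjusted p = 5.42e-07) held with an estimated correlation (adjusted p = 0.0125), and the rRNA share of the counts was 0.241% ± 0.0466 (SD, n = 3) against 0.0925% ± 0.00845 in L4440. The oocyte and early embryo list was called lower, with 1 rise and 11 falls among 40 (1 and 11 adjusted over the list alone) and small changes such as oma-2 at -0.17 (adjusted p = 5.11e-06, and adjusted p = 0.349 with an estimated correlation). Sperm genes had 0 rises and 12 falls among 43 (0 and 16 adjusted over the list alone, adjusted p = 0.00214, and adjusted p = 0.345 with an estimated correlation), with msp-45 at -1.88, a gene whose reads can be shared with its many close copies. Embryonic and larval regulators were not called (7 rose and 1 fell of 25, 7 and 2 adjusted over the list alone, adjusted p = 0.0657), with sdz-28 at 0.71 and tbx-8 at 0.95.

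Mitochondrial and ribosomal lists moved little. None of 11 mitochondrially encoded mRNAs passed edgeR's test over all genes or over the list alone (0 in both counts, median -0.12), and with the 6 libraries compared alone COX2, CYTB and ATP6 passed. Among 16 ATP synthase subunits other than atp-1, 4 fell (4 adjusted over the list alone, adjusted p = 0.0241), with an adjusted p = 0.555 with an estimated correlation and adjusted p = 0.209 under fry. That call was lost without L4440 replicate 1 (adjusted p = 0.0677), L4440 replicate 2 (0.0653) or B0395.3 replicate 3 (0.0904). Complexes II to IV had 5 falls among 24 (5 adjusted over the list alone, adjusted p = 0.00778), with an adjusted p = 0.509 with an estimated correlation and adjusted p = 0.112 under fry. The lists called higher besides histones were mitochondrial ribosomal proteins (6 rose and 1 fell of 69, 1 and 1 adjusted over the list alone, adjusted p = 0.00170, and adjusted p = 0.606 with an estimated correlation), cytosolic ribosomal proteins (3 rose of 81, 0 adjusted over the list alone, adjusted p = 0.00239, and adjusted p = 0.696 with an estimated correlation) and neuronal genes (9 rose of 54, 9 adjusted over the list alone, adjusted p = 0.00778, and adjusted p = 0.430 with an estimated correlation), the last with sbt-1 at 0.33. Under fry these 3 had adjusted p = 0.225, 0.477 and 0.0883, and the cytosolic call was lost without L4440 replicate 3 (adjusted p = 0.124).

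In all, 3976 of 14622 genes changed in B0395.3, 1836 higher and 2140 lower, of which 247 rose and 401 fell over 2-fold. The 3 libraries of each group did not overlap for 47.1% of genes, against 10% given by chance. Of the changed genes 46.2% were higher, against 67.1% of 4625 (3104 higher and 1521 lower) on RPKM with own library totals, an alternative chosen after seeing the data. Camera called 28 of 38 lists, 4 higher and 24 lower, of which 3 were left under an estimated correlation, and fry called 26. Other splits of the same 6 libraries called up to 24 lists by camera, while they called 0 genes. These splits also mixed the groups, so neither count is a rate for unchanged groups.

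The RNAi groups were also compared with each other. An embryonic gene and a ubiquitin ligase gene stood further apart than in either comparison with L4440: sdz-28 was at 45.2 ± 0.161 CPM (SD, n = 3) in B0395.3 and 1.26 ± 0.115 CPM in H28O16.1 (log2 fold change -5.15, SE 0.10, adjusted p = 4.27e-13), and skr-9 was at 53.2 ± 2.13 and 0.981 ± 0.161 CPM. Among the largest differences in favour of H28O16.1 were C07G1.7 (4.81), F57H12.6 (3.46), ora-1 (3.17) and the glycerol-3-phosphate dehydrogenase gene gpdh-1 (3.11). Of 30 histone genes 2 were higher and 24 lower in H28O16.1 (2 and 25 adjusted over the list alone), and all 6 vitellogenins were higher (6 adjusted over the list alone).

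The histone call (adjusted p = 5.68e-05) had an adjusted p = 0.0594 with an estimated correlation, and the vitellogenin call (adjusted p = 0.000259) an adjusted p = 0.529 with an estimated correlation. Also higher in H28O16.1 were antimicrobial effectors (47 higher and 15 lower of 87, 47 and 16 adjusted over the list alone, adjusted p = 0.713 with an estimated correlation), UDP-glucuronosyltransferases (36 and 10 of 60, the same adjusted over the list alone, adjusted p = 0.529 with an estimated correlation) and glutathione S-transferases (22 and 3 of 36, the same adjusted over the list alone, adjusted p = 0.136 with an estimated correlation). C-type lectins (56 and 26 of 117, 57 and 26 adjusted over the list alone, adjusted p = 0.369 with an estimated correlation) and muscle genes (18 and 7 of 29, the same adjusted over the list alone, adjusted p = 0.923 with an estimated correlation) were called higher too. Lower in H28O16.1 were mitochondrially encoded mRNAs (0 higher and 9 lower of 11, the same adjusted over the list alone, adjusted p = 0.789 with an estimated correlation), proteasome subunits (1 and 21 of 33, the same adjusted over the list alone, adjusted p = 0.923 with an estimated correlation) and endoplasmic reticulum chaperones (4 and 11 of 18, the same adjusted over the list alone, adjusted p = 0.789 with an estimated correlation). The chaperone call was lost without B0395.3 replicate 1 (adjusted p = 0.0504) or H28O16.1 replicate 2 (0.0556). In all, 9158 genes differed, 4466 higher and 4692 lower in H28O16.1. Of these 48.8% were higher, against 34.8% of 4685 genes on the deposited RPKM (1630 higher and 3055 lower) and 33.7% on log2(RPKM + 0.1) (1610 and 3163). Camera called 6 lists higher and 4 lower, 0 of them with an estimated correlation. Other splits of these 6 libraries, which mixed the groups and so give no rate for unchanged groups, called up to 19 lists and 0 genes.

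Changes in the RNAi groups overlapped, in the same and in opposite directions. Of 2620 genes changed in both groups against L4440, 1413 (53.9%) went the same way and 1207 went opposite ways, among them the aldolase gene aldo-1, higher in H28O16.1 (2.26) and lower in B0395.3 (-0.39), and fmo-2, lower in H28O16.1 (-1.91) and higher in B0395.3 (2.97). Genes higher in both numbered 557 and genes lower in both 856, where independent lists would give 484 and 668. Genes higher in H28O16.1 and lower in B0395.3 numbered 470 (564 for independent lists), and genes lower in H28O16.1 and higher in B0395.3 numbered 737 (573). Across genes, which are not independent replicates, the log2 fold changes had a Pearson r of 0.0110 and a covariance of 0.00434. In 20 simulations of unchanged groups against the same controls r averaged 0.505, the covariance averaged 0.0199 and at most 1 gene was called in both, so the observed covariance lay 0.0156 below the simulated one (difference -0.0156). The 3 controls were too few to divide, and part of the excess of genes changed the same way over independent lists may come from sharing them.

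**Figure D5:**
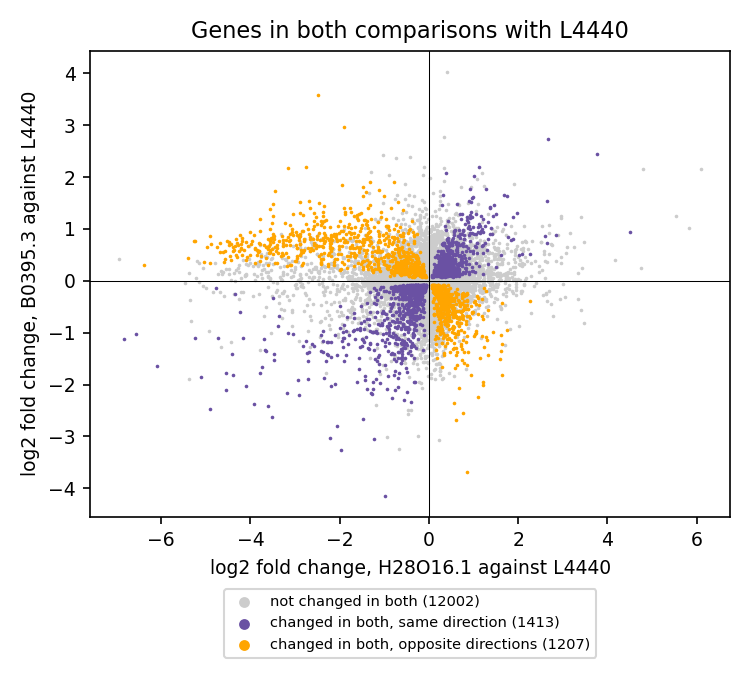
Each point is 1 of 14622 genes, placed by its log2 fold change in H28O16.1 (x axis) and in B0395.3 (y axis) against L4440, and coloured by whether it changed in both in the same direction (1413), changed in both in opposite directions (1207) or did not change in both. The group at the upper left, lower in H28O16.1 and higher in B0395.3, is part of the 737 such genes.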

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

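The directions of genes and lists in the RNAi groups were compared by planned tests, and the 4 tests of explanations and the counts of other splits here were chosen after the results they bear on had been seen. The genes and the histone list given first were taken up because they moved in opposite directions in the RNAi groups against L4440 and also differed in the direct comparison of H28O16.1 with B0395.3. Of 2620 genes changed in both groups, 1207 did so. The histone list did so as a list at the preset correlation, with a median of -0.87 in the direct comparison. With an estimated correlation only its call in B0395.3 against L4440 held (camera adjusted p = 0.0125). It was lost in H28O16.1 against L4440 (0.366) and in the direct comparison (0.0594). Among the genes named by rule 16 moved in opposite directions and also differed in the direct comparison. Those higher in H28O16.1 and lower in B0395.3 were aldo-1 (direct log2 difference 2.66), hmit-1.1 (2.69), F57H12.6 (3.46) and oac-14 (2.06). Those lower in H28O16.1 and higher in B0395.3 included the embryonic and ubiquitin ligase genes tbx-38 (-6.68), skr-9 (-5.77), fbxb-17 (-5.41), skr-8 (-5.22), sdz-28 (-5.15), sepa-1 (-4.97) and skr-10 (-4.93), for which the rise in B0395.3 was small next to the fall in H28O16.1 (0.31 against -6.37 for tbx-38). The others were T22F3.11 (-6.06), mls-2 (-4.95), fmo-2 (-4.87), Y23H5B.1 (-3.12) and zig-3 (-2.67).

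The fall of early zygotic genes in H28O16.1 was weighed first. Less RNA from embryos in or with the worms stays open: 48 zygotic genes had a median of -2.35 (3 rose and 37 fell), but most of these belong to the sdz, vet, tbx and ceh families, of which members had been seen to fall. The remaining 12 genes, separated after that, had a median of -0.68 (2 rose and 6 fell), between the bounds of -1 and -0.5 set for the presence and absence of such an effect. Fewer embryos, arrested embryos, weaker transcription within embryos and a response of the worm itself to atp-1 RNAi may each give this picture and were not separated.

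The opposite movement of histones was weighed next, with carry-over of RNA without poly(A), which would bring in the replication-dependent histone mRNAs, as the technical explanation. The 10 histone variants and linker histones, whose mRNAs carry poly(A), had medians of 0.45 in B0395.3 (8 rose and 0 fell) and -0.56 in H28O16.1 (1 rose and 7 fell), which argues against carry-over as the whole source. Of these hil-3, his-24, hil-2, his-71 and his-72 had already been seen to lead the list, and the other 5 were less clear, with 3 rises and 0 falls in B0395.3 (median 0.21) and 1 rise and 2 falls in H28O16.1 (median -0.092, with hil-1 at -0.99). The rRNA share, which less carry-over would lower, went against it in H28O16.1 and with it in B0395.3: it was 0.206% to 0.294% in B0395.3 against 0.0869% to 0.102% in L4440, and 0.290% and 0.317% in replicates 1 and 3 of H28O16.1 but 0.107% in replicate 2. A median of 0.13 over the same 12 zygotic genes goes with more RNA from embryos in B0395.3 (4 rose, 0 fell and 8 did not pass). That shift is smaller than the histone median of 0.28, and camera gave the 12 genes an unadjusted p of 0.0515 (0.299 with an estimated correlation). All 48 zygotic genes, most of them of the families seen before, had a median of 0.16 in B0395.3 (17 rose and 3 fell). Camera gave the 48 genes an unadjusted p of 0.000295 (0.0464 with an estimated correlation). The oocyte and early embryo list went the other way in B0395.3, with 1 rise and 11 falls among 40 (camera adjusted p = 5.11e-06, and 0.349 with an estimated correlation). A response to the RNAi treatments themselves was not tested apart from embryo content.

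Other splits of the libraries were counted for each comparison. In each pair of groups 1 of the 10 splits of the 6 libraries, the real one, called the real number of genes (8417, 3976 and 9158), and the highest other split called 0. With 10 splits no share under 0.05 can be had. For lists, 5 of 10 splits in H28O16.1 against L4440, 1 of 10 in B0395.3 against L4440 and 6 of 10 in the direct comparison called as many as the real split (11, 28 and 10), and the highest other splits called 18, 24 and 19. List calls at the preset correlation were thus made in splits without a single gene call. Each other split mixed the groups compared, so it kept part of their difference and counted the rest as spread. These counts of genes and lists therefore give no rate for unchanged groups. Among 100 splits drawn of the 9 libraries into 3 groups, 1, the real one, reached the 10121 genes that differed among groups. The highest other called 6463. That share is under 0.05, but it bears only on how these libraries group. Splits that mix groups count the differences between groups as spread within groups. No split can tell the RNAi treatment from anything else that the libraries of a group share. For genes changed in both groups, each split was counted with each of its groups as the control in turn. Of these 300 counts 6 reached the real 2620. The counts of a split are not independent of each other, and splits with other groups reached 2620 too, so no conclusion on chance is drawn for that count. Nor do these counts test whether the RNAi groups share changes. Of the 6, 3 came from the real groups, the highest with another group as control at 7062, and 3 from splits that kept H28O16.1 whole, the highest at 6019, which points to the distance of H28O16.1 from all other libraries as the structure behind them.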

How the results depend on the processing

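RPKM with own library totals and the counts without rRNA and mitochondrial genes were chosen after seeing the data, and all other alternatives before the data were examined. No named gene or target reversed under RLE factors, DESeq2 (where it gave an adjusted p), the 6 libraries compared alone or with 1 library left out, no target on the deposited log2(RPKM + 1), and no called list under fry, RLE factors or with 1 library left out. The other alternatives were run for counts of genes only. The balance of higher and lower calls reversed in part. On RPKM with own library totals it turned from 3851 higher and 4566 lower to 4560 and 3972 in H28O16.1 against L4440, and from 1836 and 2140 to 3104 and 1521 in B0395.3 against L4440, which also stood at 819 and 779 on the deposited log2(RPKM + 1). RPKM carries no TMM scaling. With own totals its log2 fold changes lay above the main ones by a median of 0.0509 and 0.0592 in these comparisons. TMM factors were 0.964 to 0.983 in L4440 and 0.993 to 1.02 in the RNAi groups, so leaving them out raises the RNAi groups relative to L4440. The part played by the other test and the added 1 was not separated. The counts of changed genes, given for H28O16.1 against L4440, B0395.3 against L4440 and H28O16.1 against B0395.3 (8417, 3976 and 9158), fell by more than 1.5 times under 3 settings. Testing against a fold of 1.5 left 1842, 567 and 2554, as that test asks for larger changes. The deposited RPKM gave 3622, 1598 and 4685 on log2(RPKM + 1) and 3752, 1556 and 4773 on log2(RPKM + 0.1). With own library totals the same test gave 8532, 4625 and 9091, so the loss went with the totals used. DESeq2 gave 7696, 3309 and 8374, and leaving out rRNA and mitochondrial genes gave 8406, 3975 and 9149. With 1 library left out the counts ranged from 7740 to 8644, from 2943 to 3268 and from 8398 to 9341. Genes differing among the 3 groups ranged from 9540 to 10434, and genes changed in both RNAi groups from 1885 to 2054 with 1 L4440 library left out, against 2620. For the targets the log2 fold change ranged from -4.83 to -4.74 for atp-1 and from -1.41 to -1.2 for B0395.3 with 1 library left out, and B0395.3 was at -1.12 on the deposited RPKM.

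Of 352 results for single genes, 328 were the same under every alternative run for them. DESeq2 ended 3 calls, all in B0395.3 against L4440: msp-33, msp-49 and gsp-3 (DESeq2 adjusted p = 0.114, 0.0732 and 0.0630). With the 6 libraries compared alone 6 more passed. Of 49 list calls, an estimated correlation ended 46, fry 5, RLE factors 0 and leaving out 1 library 4. No paired analysis was possible because the labels give no number shared between groups. At depths of 31236614 to 40990685 counts per library, genes removed by the filter on low counts were not tested, and with 3 libraries per group changes of 1.5-fold were recovered in part on simulated counts (67.2% in H28O16.1 against L4440 and 70.1% in B0395.3 against L4440).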

Other observations

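The tests of gene families and of explanations for the fall of acdh-1 here were chosen after the main results had been seen, and genes of a family are not independent. Families of gene symbols with at least 10 tested genes (132 families) were asked whether more of their members changed over 2-fold than other genes, by Fisher's exact test with adjustment over families. In H28O16.1 10 families were enriched among falls and 0 among rises. The F-box family fbxb stood out, with 90 of 94 tested genes (95.7%, against 7.81% of other genes) lower over 2-fold and a median of -3.16. The others were fbxc (20 of 34), the zygotic family sdz (23 of 28), the T-box family tbx (10 of 14), the Skp1-related family skr (9 of 19), the homeobox family ceh (10 of 43), the major sperm proteins msp (12 of 12), col (47 of 103), dpy (7 of 24) and his (7 of 23). Reads of close copies within fbxb, fbxc, skr, msp and his can be shared, so their members are fewer independent measurements than their number.

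In B0395.3 8 families were enriched among falls over 2-fold: col (44 of 103), cyp (13 of 63), ugt (11 of 60), clec (14 of 117), msp (5 of 12), gst (7 of 36), the aspartic proteases asp (4 of 11) and the dehydrogenases dhs (5 of 30). The insulin-like peptide family ins was the 1 family enriched among rises, with 5 of 26 tested genes higher over 2-fold against 1.66% of other genes (Fisher's exact test, adjusted p = 0.00859). Among these ins-2 rose by 1.91 log2 units (from 2.01 to 7.61 CPM) and ins-23 by 1.70 (from 0.435 to 1.4 CPM), both chosen after their values were seen. In H28O16.1 the family was not enriched in either direction, and the difference between the groups was not tested for the family.

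The fall of the propionate shunt gene acdh-1 in both RNAi groups was weighed since both comparisons use the same controls. The list of propionate and methionine metabolism was called lower in both, but not with an estimated correlation (camera adjusted p = 0.783 in H28O16.1 and 0.114 in B0395.3). A single L4440 library as the source is argued against, because the smallest fall of acdh-1 over both comparisons, whichever L4440 library was left out, was -2.14 on the log2 scale. More vitamin B12 from the bacteria, which lowers acdh-1 and methionine cycle genes alike, stays open. Of 7 methionine cycle genes, 4 fell and 0 rose in B0395.3, and 3 fell and 2 rose in H28O16.1. These falls are fewer than the 5 that it was taken to need and more than the 1 taken to exclude it. The transporter gene pmp-5 fell most among them, by 1.70 and 1.57 log2 units, and the methionine synthase gene metr-1 stood at 0.014 in B0395.3 and rose by 0.18 in H28O16.1. An L4440 culture that differed from both others may also give this picture and was not tested.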
